A study of Rattus norvegicus with 6 samples.

How the data were processed

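Poly(A) RNA from primary nucleus pulposus cells of Sprague Dawley rats was sequenced in 6 samples, 3 given recombinant Sonic hedgehog (rShh) at 200 ng/ml for 48 h and 3 given DMSO. Per the labels' protocols, cells were kept in DMEM/F12 with 10% fetal bovine serum, RNA with an integrity number above 7.0 was used, and libraries were made with dUTP marking of the second strand, amplified over 8 PCR cycles and sequenced as 150-nt paired-end reads. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, DESeq2 and edgeR were used. Their roles, settings, the strand setting of the counting and the genome build are not given in the sources used here. Coordinates are those of the deposited tables.

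The authors deposited a gene table of 19088 rows and an isoform table of 24343 rows, each with whole-number counts and FPKM values per sample. The deposited counts are not normalized. The deposited FPKM values are, per the file headers, fragments scaled to transcript length and library size (FPKM). Their scaling implies totals 1.17 to 1.20 times the summed gene counts, so the FPKM values were not computed from those sums. Gene counts equalled the sum of the isoform counts in 99.998% of values. Every gene row carried a name, a placeholder in 3282 rows, so none was left out as nameless. The lowest summed count of a gene row was 1, so genes without any count are not in the table. Gene symbols came from the files, and 446 symbols stood on more than 1 row; rows were kept apart by gene ID. The reference gene table was not used, since none of its identifiers matched. Genes with near-identical copies, such as the MHC genes or Ddx3 and Ddx3x, and overlapping genes can share reads, so their values are uncertain.

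The design fixed before the data were examined assumed FPKM values alone and named edgeR as the gene test if counts were present. They were, so genes were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10 and scaled by TMM. They were tested with glmQLFit and glmQLFTest, two-sided, with group as the only term. Isoforms were tested with limma 3.58.1 (trend) on log2(FPKM + 1) for rows with a mean of at least 1 FPKM. Fold changes on that scale understate the change of low isoforms. P-values were adjusted by Benjamini and Hochberg's method, with a threshold of 0.05. Gene values are TMM-scaled CPM, as mean ± SD over 3 samples. A fold against a group at 0 in all libraries is a lower bound against a floor of 3 counts per library, which is 0.043 to 0.059 CPM. Floors cover counting error only.

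Fixed before the data were examined, 33 gene lists covered Hedgehog targets, Hedgehog pathway components, nucleus pulposus, matrix, protease, tendon, osteogenic, inflammatory, interferon, signalling, cell cycle, stress and metabolic genes, and markers of other cell types. The 29 lists with at least 3 members above 1 FPKM were tested with limma's camera at its preset correlation of 0.01 on log2(FPKM + 1), which compares a list with the other genes. The fry test, which asks whether a list's own genes move, was run beside it. Camera and fry used only members with a mean of at least 1 FPKM, while counts of rises and falls cover all members tested with edgeR. Camera had 5 genes in the Notch list, where edgeR tested 12. It had 3 in the muscle list and 3 in the epithelial list, where edgeR tested 6 and 8. The Hedgehog target score is the mean log2(FPKM + 1) of that list's members, compared by an exact permutation test. The genes named are the Hedgehog genes Gli1, Ptch1, Hhip, Smo, Gli2, Gli3 and Shh, the 12 largest increases and decreases with separate groups and a gene symbol, the members of each list with the smallest p (up to 3), and the 3 isoforms with the smallest p in each direction. Some genes that this rule takes are not reported here. Other genes are said to have been chosen after their values were seen. Kdm5c, Kdm6a and Ddx3x were chosen after the Y-linked counts but before their own values were seen. Eif2s3 was chosen after its values were seen, as were Aqp1, Col18a1, Igfbp2, C1qtnf3 and Npr3 as genes, which follow the named isoforms.

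Replicates were compared before averaging. Over genes with at least 100 counts in a pair, the chi-square per degree of freedom was 10.5 to 50.5 within groups, far above sampling noise, so no library was counted as a repeat of another. The edgeR fit had a common biological coefficient of variation of 12.7%.

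The tests were checked on simulated counts drawn from the libraries' own means, with 200 changed genes. For rShh against Control over 14530 genes, edgeR recovered 60% of 1.5-fold, 78% of 2-fold, 88% of 4-fold and 94% of 8-fold changes, with 9 false calls (5.33% of its calls). DESeq2 recovered 64%, 82%, 92% and 92% over 14775 genes, with 32 false calls (16.2%). Limma on log2(FPKM + 1) recovered 62%, 78%, 78% and 76% over 11712 genes, with 11 false calls (6.96%). Only 200 genes were changed here, as many up as down, while in the data 60.3% of the genes tested were called. Scaling and false calls under changes that widespread were not checked. In simulated lists of 20 genes, camera called the changed list and 1 of the 29 unchanged ones. The simulated genes were drawn independently of each other, so this check does not test the preset correlation of 0.01. In the data the correlation was estimated at 0.26 for the inflammatory list and 0.94 for the mitochondrially encoded mRNAs. It was -0.015 for the fibrillar collagen and myofibroblast list.

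Alternatives covered the pseudocount, expression minimum, scaling, variance model, tool (limma on FPKM, DESeq2 1.42.0), a replicate block, each replicate left out, and for the lists an estimated correlation and fry. Thinning every library to the smallest total, a test against 2-fold, camera on log2 CPM, edgeR on isoform counts and leaving out the sex chromosomes were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.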

Results

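Gene expression was measured by poly(A)-selected RNA sequencing in primary nucleus pulposus cells, the cells of the gelatinous core of the intervertebral disc, taken from Sprague Dawley rats. Of the 6 samples, 3 had received recombinant Sonic hedgehog (rShh), the secreted ligand that starts Hedgehog signalling, at 200 ng/ml for 48 h. The other 3 had received its solvent, DMSO, and are called Control. Counts over genes summed to 50758195 to 55501124 per library in the Control group and to 65116846 to 70031072 in the rShh group. The Control libraries had counts for 15878 to 16034 genes and the rShh libraries for 16691 to 16916. Mitochondrial transcripts took 1.97% to 2.28% of the counts in the Control libraries and 3.25% to 3.36% in the rShh libraries. The labels do not say that the 3 samples of a group came from separate cultures or animals, so the p-values measure the spread between these samples, which may be technical.

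The groups also differed in transcripts of the Y chromosome. Ddx3 (the file's name for a gene at 1217800 to 1238420 on chromosome Y), Eif2s3y (914045 to 933699), Kdm5d (505996 to 589267) and AC241873 (989240 to 1206096) had 0 counts in each of the 3 Control libraries. In the rShh libraries Ddx3 had 6357 to 7120 counts, Eif2s3y 3871 to 4159, Kdm5d 2235 to 2335 and AC241873 912 to 1054. Set against a floor of 3 counts in each Control library, Ddx3 was at least 1776-fold higher in the rShh group and Eif2s3y at least 1064-fold higher. Of 9 Y-chromosome genes tested, 2 had counts above 50 in every library of both groups (AC242859 at 602419 to 603067 and AC242953). Among related genes on chromosome X, which were picked for being Y-gene partners, Kdm5c fell from 158 ± 12.3 to 87.0 ± 5.66 CPM (read counts scaled to library size; mean ± SD, n = 3) and Eif2s3 from 165 ± 12.2 to 129 ± 4.08. Ddx3x rose from 286 ± 39.4 to 654 ± 15.9 CPM, and Kdm6a was at 26.1 ± 3.29 and 25.0 ± 1.27 CPM. Ddx3 and Ddx3x are similar in sequence and may share reads, so their separate values are uncertain. The labels give no sex, and the presence of Y transcripts coincided with the treatment in all 6 libraries. Every comparison below therefore compares groups that differed in this respect as well as in the ligand, and the 2 cannot be told apart here.

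**Figure D1:**
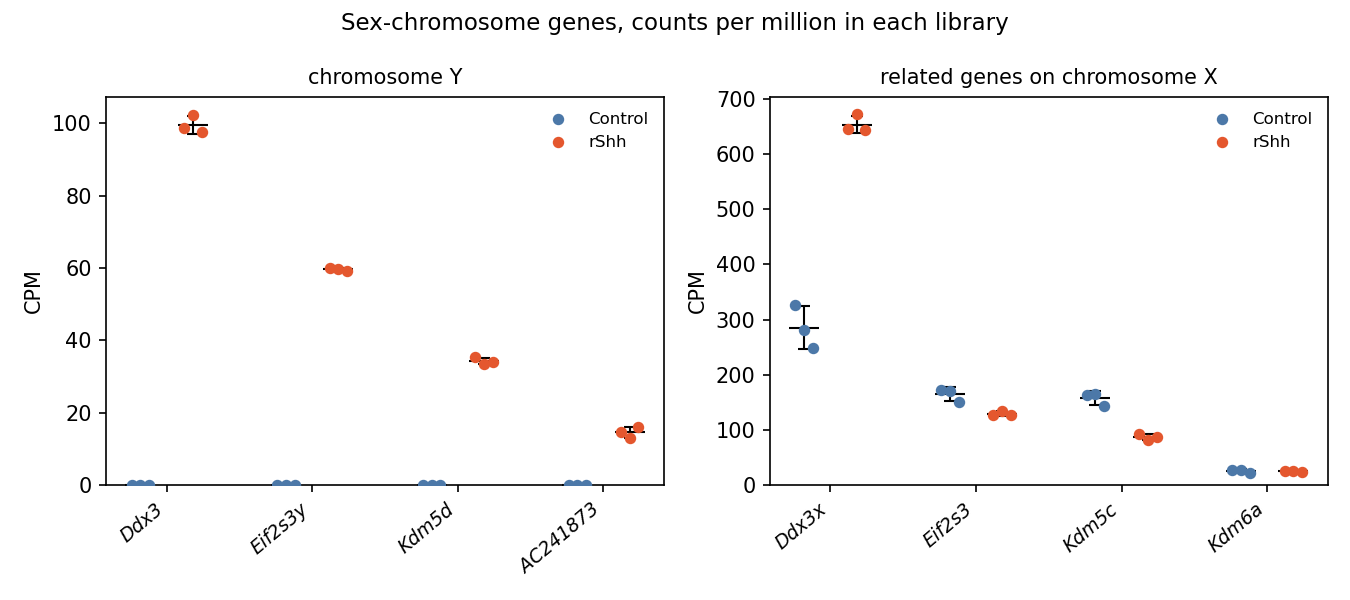
Scaled read counts (CPM) of 4 Y-chromosome genes (left) and of 4 related X-chromosome genes (right) on linear axes, with 1 point per library, a bar at the group mean and whiskers of 1 SD (n = 3). The Y-chromosome genes lie at 0 in the 3 Control libraries and between 14.6 and 99.5 CPM on average in the rShh libraries.

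The first comparison asked which genes differed between cells given rShh and cells given its solvent. The changes were widespread and went both ways. Aqp1, a water channel, rose from 2.56 to 602 CPM, and Col18a1, a basement membrane collagen, from 36.9 to 1222 CPM. Igfbp2, which binds insulin-like growth factors, fell from 162 to 6.28 CPM, and Npr3, the clearance receptor for natriuretic peptides, from 137 to 6.08 CPM. Of 14775 genes tested with edgeR's quasi-likelihood test, 8914 (60.3%) changed at an adjusted p below 0.05, 4657 of them higher and 4257 lower in the rShh group. The balance of directions depended on the scaling, since limma on FPKM gave 4002 higher and 3964 lower, 3939 and 4054 with median-ratio scaling, and 3599 and 4502 after quantile normalization. Of the 8914 genes called by edgeR, 1921 were at least 2-fold higher and 843 at least 2-fold lower. A test against a change of 2-fold, added after the data were seen, called 1563 genes, 1176 higher and 387 lower. For 10065 of the 14775 genes (68.1%) the 3 values of 1 group all lay above the 3 of the other, where chance gives 10%. Correlations of log CPM were 0.976 to 0.987 within groups and 0.908 to 0.916 between them.

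The 12 genes named for the highest fitted log2 change had 0 counts in all Control libraries. The fit adds a small prior count, which puts genes at 0 in 1 group first, so this order does not rank them against genes measured in both groups, such as Aqp1 (235-fold). After the 4 Y-chromosome genes came Crabp1, a retinoic acid binding protein, at 5.40 ± 0.259 CPM in the rShh group and at least 96.3-fold higher than the floor of 3 counts per Control library. Ulbp1, a ligand of the NKG2D receptor, reached 5.08 ± 0.336 CPM and Spink8 3.44 ± 0.452. Ciita, the master regulator of MHC class II transcription, reached 3.41 ± 0.330 CPM and was at least 60.9-fold higher. Arntl2, a clock gene paralogue, reached 3.10 ± 0.181 CPM. Ptprb, Slc14a1 (a urea transporter) and Rgs4 followed at 2.51 ± 0.290, 2.26 ± 0.913 and 2.07 ± 0.305 CPM. Among the 12 genes named for the lowest fitted log2 change, to which the same limit applies, Barx1, a homeobox transcription factor of developing mesenchyme, had 1510 to 2214 counts in the Control libraries and 0, 0 and 8 in the rShh libraries, or 35.3 ± 7.64 and 0.041 ± 0.071 CPM. Synpr and Ptchd1, at 3.04 ± 0.927 and 2.30 ± 1.24 CPM in the Control group, had 0 counts in the rShh libraries, which put Synpr at least 67.4-fold lower. Pde1c (a phosphodiesterase) and Efemp1 (an extracellular matrix glycoprotein) had 2.03 ± 0.153 and 1.83 ± 1.13 CPM in the Control group and 0 counts in the rShh group. Syt14, Plet1, Rnf151, Cmtm5, Nell1 and Cntn5 lay below 1 CPM in the Control group and had 0 counts in the rShh libraries. Gm27733 fell from 2.09 ± 0.799 CPM to a single count in 1 rShh library.

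Ptch1, the Hedgehog receptor and itself a transcriptional target of the pathway, was higher in the rShh group. It lies on chromosome 17 at 1029048 to 1093873, on the minus strand, and rose from 12.5 ± 1.65 to 32.6 ± 1.61 CPM (log2 change 1.38, SE 0.11, edgeR adjusted p = 2.42e-06), a 2.61-fold difference present in all libraries. Smo, the receptor component that Ptch1 holds in check (chromosome 4, 57019941 to 57042770), fell from 50.0 ± 1.49 to 27.2 ± 0.839 CPM. Gli3, which mostly acts as a repressor of Hedgehog targets, fell from 28.0 ± 4.48 to 18.6 ± 0.396 CPM. Gli2 was at 10.0 ± 1.71 and 8.65 ± 1.33 CPM and did not pass the test. Gli1, the most widely used readout of the pathway, had few counts, with 22, 0 and 0 in the Control libraries and 25, 35 and 30 in the rShh libraries (edgeR adjusted p = 0.200). Control replicate 1 decided this value, since without it the edgeR adjusted p was 0.00131. Hhip had too few counts to be tested, and the transcript of Shh was not analysed here.

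**Figure D2:**
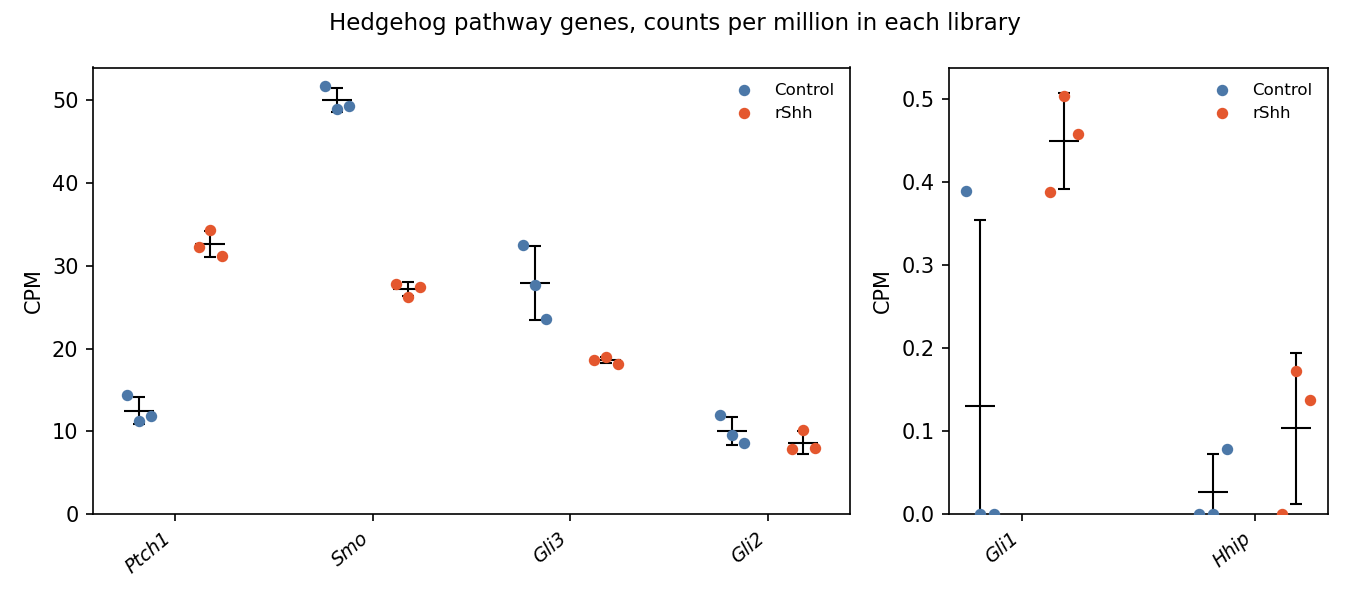
Scaled read counts (CPM) of Hedgehog pathway genes on linear axes, more abundant genes on the left and genes with few counts on the right, with 1 point per library, a bar at the mean and whiskers of 1 SD (n = 3). Ptch1 rose from a mean of 12.5 to 32.6 CPM while Smo and Gli3 fell, and Gli1 and Hhip overlapped between the groups.

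Of 14 tested transcriptional targets of Hedgehog signalling, 6 rose, 2 fell and 6 did not pass. Among all genes tested, 31.5% rose and 28.8% fell. The largest increases were in Hsd11b1, which regenerates active glucocorticoid (17.1 ± 1.80 to 137 ± 5.77 CPM), and Prdm1, a transcriptional repressor (6.81 ± 0.887 to 25.1 ± 3.33 CPM). As a set the targets did not stand apart from the other genes (camera adjusted p = 0.144). The Hedgehog target score, the mean log2(FPKM + 1) of the 10 targets above the expression minimum, was 2.60 ± 0.06 in the Control group and 3.14 ± 0.02 in the rShh group. The difference of 0.54 was present in all libraries, and its two-sided exact permutation p of 0.1 is the smallest that 3 samples against 3 allow. The difference was 0.29 with no expression minimum and 0.97 with a minimum of 5 FPKM. Hsd11b1, with an edgeR log2 change of 3.01, is among the 10 members, so a few genes can carry much of the score. Of 21 tested ligands, receptors and transducers of the pathway, 4 rose, 9 fell and 8 did not pass (camera adjusted p = 0.742). Scube3, which helps release Hedgehog ligands, rose from 16.8 ± 1.56 to 55.9 ± 2.06 CPM, and Gpc6, a glypican, fell from 38.5 ± 2.49 to 18.5 ± 1.36 CPM.

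Genes of cell division were higher in the rShh group with few exceptions. All 31 tested G2/M mitosis genes rose, with a median log2 change of 2.07. Cenpf, a kinetochore protein, rose from 6.83 ± 0.264 to 62.7 ± 2.13 CPM, Top2a, the topoisomerase that untangles chromosomes, from 15.3 ± 1.97 to 105 ± 4.24, and Prc1, a midzone protein of the dividing cell, from 16.0 ± 1.32 to 90.4 ± 0.233. Of 27 tested G1/S replication genes, 26 rose and 1 did not pass, with a median log2 change of 1.17. Rrm2, which makes deoxynucleotides, rose from 10.6 ± 0.429 to 58.6 ± 4.30 CPM, Ccne2, a cyclin of S-phase entry, from 4.40 ± 0.274 to 28.4 ± 2.64, and Pcna, the replication clamp, from 28.6 ± 0.770 to 69.8 ± 2.80. The G2/M and G1/S lists passed the camera test with its preset correlation (adjusted p = 2.7e-14 and 9.84e-09). Neither passed with an estimated correlation, where the camera adjusted p was 0.0848 for both. Among p53 and senescence genes, which restrain division, 6 rose, 10 fell and 5 did not pass (camera adjusted p = 0.742). The cell cycle inhibitor Cdkn1a fell from 684 ± 28.8 to 331 ± 7.41 CPM, while Btg2 rose from 38.1 ± 2.33 to 187 ± 8.26 and Igfbp3 from 2.01 ± 0.441 to 20.6 ± 0.871.

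Markers of nucleus pulposus cells did not move together. Of 17 tested, 7 rose, 9 fell and 1 did not pass, with a median log2 change of -0.39. Camera used the 12 above 1 FPKM and gave the direction up (adjusted p = 0.978). Hif1a, the oxygen-sensing transcription factor that is constitutively present in this tissue, rose from 78.6 ± 7.35 to 253 ± 9.01 CPM. Cd24, a surface marker of nucleus pulposus cells, fell from 51.2 ± 3.80 to 15.4 ± 1.09 CPM and Fgf10, a growth factor, from 303 ± 28.0 to 82.9 ± 6.62. Krt8, a keratin of notochordal cells, fell from 12.6 ± 0.771 to 2.11 ± 0.243 CPM, and Foxa2, a notochord transcription factor, from 2.09 ± 0.387 to 0.588 ± 0.137 CPM. These 2 genes were chosen after their values were seen. The list's log2 changes ran from -4.73 to 5.90, so the 2 falls do not stand for the list.

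Among genes of cartilage-type matrix, 6 of 21 tested rose, 9 fell and 6 did not pass. Acan, the core protein of aggrecan, the main proteoglycan of the disc, rose from 56.5 ± 7.97 to 586 ± 14.5 CPM, or 10.4-fold. Prelp, a leucine-rich proteoglycan, rose from 26.9 ± 3.27 to 173 ± 3.85 CPM, and Col11a1 fell from 5419 ± 452 to 2327 ± 54.9 CPM. Of genes chosen after their values were seen, Sox9, the main transcription factor of cartilage, rose from 2.34 ± 0.326 to 4.67 ± 0.229 CPM and Col2a1, the main collagen of cartilage, fell from 1.61 ± 0.109 to 0.107 ± 0.139 CPM. The list's median log2 change was -0.15 over the 21 tested. Camera used the 11 members above 1 FPKM and gave the direction up (adjusted p = 0.742). Of 26 fibrillar collagen and myofibroblast genes, 10 rose (11 adjusted over the list alone), 12 fell and 4 did not pass (camera adjusted p = 0.990). Their mean log2 change was 0.11, while camera gave the direction down. Postn, a matrix protein of remodelling tissue, rose 12.2-fold, from 349 ± 27.7 to 4273 ± 101 CPM. Col12a1 fell from 10827 ± 1046 to 1488 ± 23.7 CPM and Col1a1, the most abundant collagen of fibrous tissue, from 35166 ± 1559 to 16390 ± 417.

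Matrix-degrading proteases rose more often than they fell, at 14 up, 5 down and 3 not passing of 22 tested (camera adjusted p = 0.00869). With an estimated correlation the camera adjusted p was 0.559. Mmp3, stromelysin, rose from 21.9 ± 1.91 to 153 ± 8.19 CPM, and the plasminogen activators Plau and Plat rose from 4.89 ± 0.344 to 41.1 ± 1.95 and from 61.8 ± 1.3 to 244 ± 6.31. Of 15 hypertrophic and osteogenic markers, 10 rose, 1 fell and 4 did not pass (camera adjusted p = 0.00309, from the 9 above 1 FPKM). With an estimated correlation the camera adjusted p was 0.416. Ibsp, bone sialoprotein, rose from 1.37 ± 0.624 to 112 ± 2.40 CPM, Spp1, osteopontin, from 1167 ± 50.0 to 4190 ± 105, and Ankh, a pyrophosphate transporter, from 21.3 ± 0.924 to 145 ± 4.30. Of 11 annulus fibrosus and tendon markers, 7 rose (8 adjusted over the list alone), 2 fell and 2 did not pass (camera adjusted p = 0.0639). Thbs4, a tendon matrix protein, rose from 0.551 ± 0.301 to 36.9 ± 0.234 CPM, and Fibin from 33.0 ± 2.56 to 86.7 ± 2.20.

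**Figure D3:**
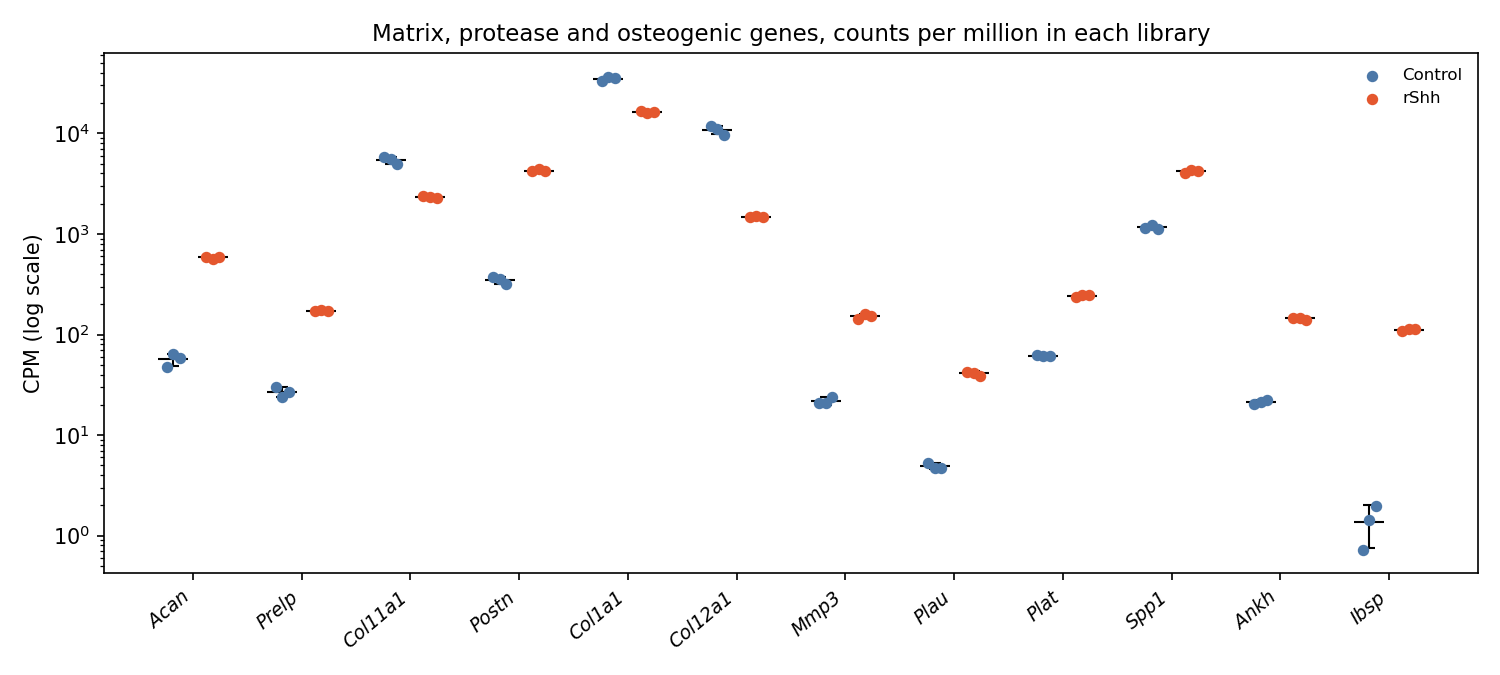
Scaled read counts (CPM, log axis) of the named matrix, protease and osteogenic genes, with 1 point per library, a bar at the mean and whiskers of 1 SD (n = 3). Acan, Prelp, Postn, the 3 proteases and the 3 osteogenic genes were higher in the rShh libraries, and Col11a1, Col1a1 and Col12a1 lower, with no overlap between the groups.

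Of 33 tested inflammatory cytokines, chemokines and NF-kB targets, 20 rose (21 adjusted over the list alone), 6 fell and 7 did not pass (camera adjusted p = 0.00309). With an estimated correlation the camera adjusted p was 0.559. Cxcl12, a chemokine that attracts leukocytes and progenitors, rose from 2.67 ± 0.858 to 262 ± 21.6 CPM. Ptgs2, cyclooxygenase 2, rose from 291 ± 21.6 to 1778 ± 120 CPM, and Tnfaip6, a hyaluronan-binding protein induced by inflammation, from 6.68 ± 0.547 to 72.9 ± 5.09. Interferon response genes went both ways, with 5 of 23 higher, 7 lower (6 adjusted over the list alone) and 11 not passing (camera adjusted p = 0.198). Their mean log2 change was 0.20, while camera, which used the 14 above 1 FPKM, gave the direction down. The guanylate-binding proteins Gbp2 and Gbp5 fell from 17.5 ± 1.26 to 3.56 ± 0.369 and from 9.39 ± 0.992 to 2.04 ± 0.309 CPM. Of 26 immediate early genes, 17 rose, 7 fell (8 adjusted over the list alone) and 2 did not pass (camera adjusted p = 0.0529). This list passed without Control replicate 2, rShh replicate 2 or rShh replicate 3 (camera adjusted p = 0.0329, 0.0394 and 0.0418), but not with an estimated correlation (camera adjusted p = 0.610). With the preset correlation it also passed after quantile normalization and on log2 CPM (camera adjusted p = 0.0174 and 0.0314). Egr1 rose from 17.7 ± 3.76 to 286 ± 19.3 CPM and Nr4a3 from 1.24 ± 0.077 to 11.3 ± 0.710.

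Of 31 hypoxia and glycolysis genes, 25 rose, 1 fell and 5 did not pass (camera adjusted p = 4.69e-06). With an estimated correlation the camera adjusted p was 0.502. Bnip3, a mitophagy receptor induced by low oxygen, rose from 112 ± 8.91 to 395 ± 23.5 CPM, Ldha, lactate dehydrogenase A, from 741 ± 39.3 to 1744 ± 23.9, and Higd1a from 40.8 ± 1.52 to 110 ± 2.87. All 13 mitochondrially encoded mRNAs rose, with a median log2 change of 0.72 (camera adjusted p = 6.2e-05). With an estimated correlation the camera adjusted p was 0.559. Mt-nd2 rose from 731 ± 58.7 to 1456 ± 32.7 CPM and Mt-co3 from 2073 ± 181 to 3844 ± 82.3. Of 30 genes of the unfolded protein response, 7 rose (8 adjusted over the list alone), 18 fell and 5 did not pass (camera adjusted p = 0.0639). Trib3, Herpud1 and Phgdh fell from 160 ± 13.4 to 57.8 ± 2.92, from 243 ± 10.9 to 111 ± 0.878 and from 201 ± 13.7 to 92.3 ± 4.14 CPM.

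**Figure D4:**
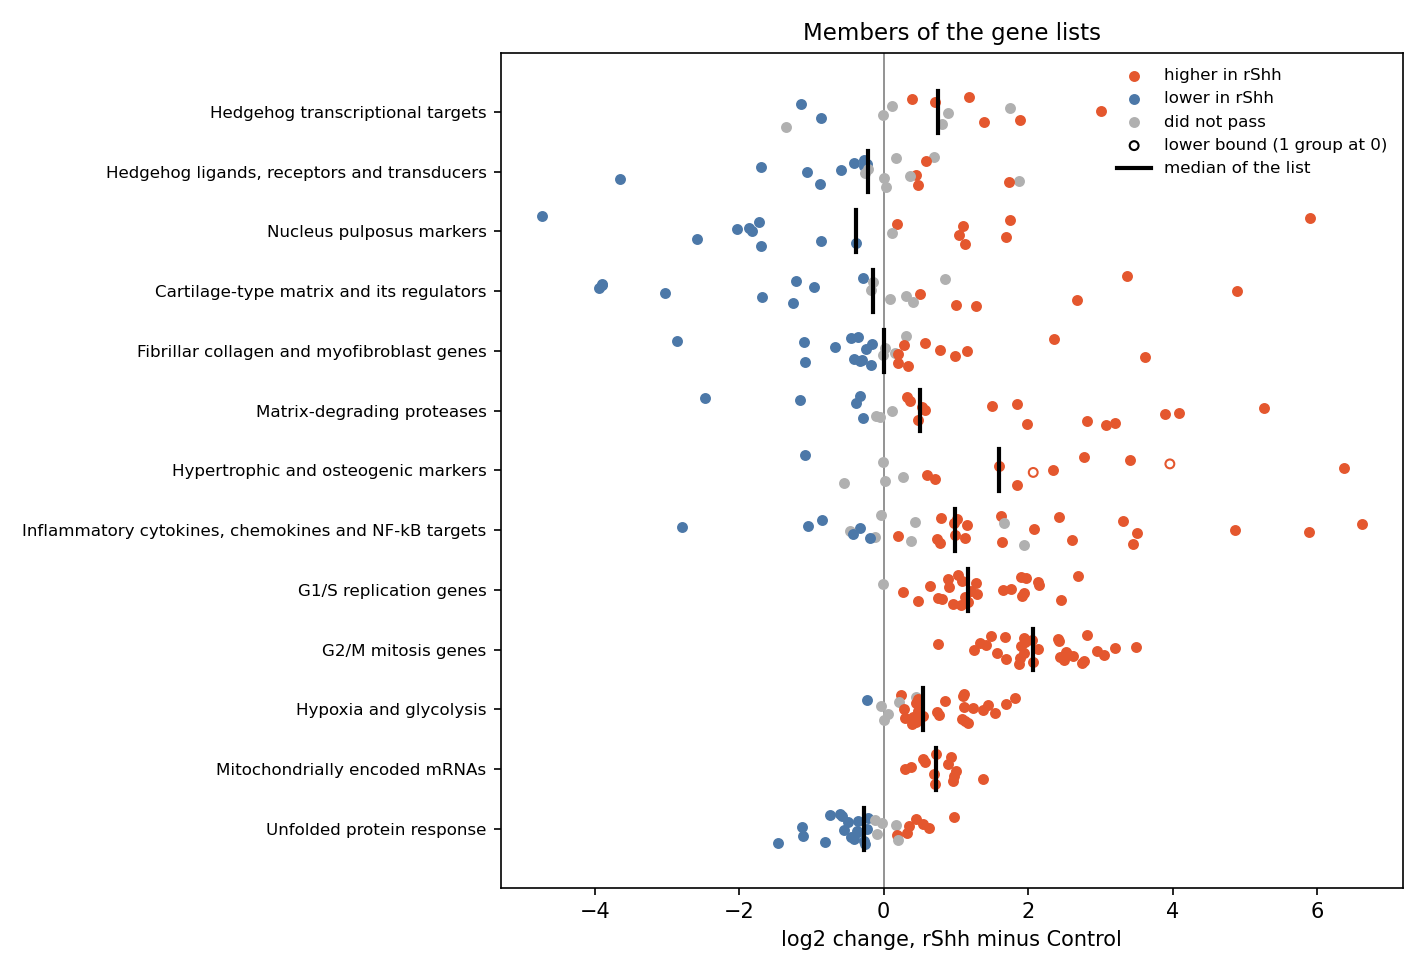
Log2 change (rShh minus Control) of each tested member of 13 gene lists, with 1 point per gene coloured by its edgeR call, open points for lower bounds of genes at 0 in 1 group, and a black line at the median. All 31 G2/M mitosis genes lie above 0, with a median of 2.07, while the markers of nucleus pulposus cells lie on both sides of 0.

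Other signalling and stress lists moved in both directions, and none passed the camera test at its main settings. Of 25 TGF-beta and BMP targets, 15 rose, 7 fell and 3 did not pass (camera adjusted p = 0.105, and 0.0352 with quantile normalization). The BMP antagonist Grem1 rose from 1074 ± 99.95 to 3906 ± 27.6 CPM, and Skil, a repressor of TGF-beta signalling, from 31.7 ± 1.66 to 79.1 ± 0.733. Of 19 Wnt targets and antagonists, 6 rose, 6 fell and 7 did not pass (camera adjusted p = 0.990). The feedback inhibitor Axin2 fell from 160 ± 9.44 to 27.9 ± 0.885 CPM, while Nkd2 rose from 60.6 ± 4.61 to 234 ± 2.80 and Dkk3 from 243 ± 12.4 to 678 ± 11.4. Of 12 Notch targets and pathway genes, 5 rose, 2 fell and 5 did not pass (camera adjusted p = 0.716). Notch1 and Hes1 fell from 15.1 ± 0.641 to 7.04 ± 0.544 and from 24.0 ± 2.96 to 14.2 ± 1.07 CPM, while Hey2, a Notch target, rose from 2.15 ± 0.055 to 6.13 ± 0.416. Among 23 apoptosis regulators, 10 rose, 8 fell and 5 did not pass (camera adjusted p = 0.990). The survival gene Bcl2l1 fell from 110 ± 3.87 to 55.2 ± 2.41 CPM and the pro-apoptotic Bax from 138 ± 14.2 to 68.8 ± 2.13, while Cflar, an inhibitor of caspase 8, rose from 15.9 ± 3.11 to 58.4 ± 1.32. Of 28 NRF2 antioxidant genes, 8 rose and 12 fell (9 and 13 adjusted over the list alone), and 8 did not pass (camera adjusted p = 0.851). Their median log2 change was -0.082 and their mean 0.032, with the camera direction down. Sod2 rose from 95.9 ± 9.31 to 316 ± 14.7 CPM and Hmox1 from 305 ± 34.7 to 678 ± 17.7. Of 23 cholesterol synthesis genes, 6 rose, 11 fell and 6 did not pass (camera adjusted p = 0.393), with Fdps falling from 172 ± 14.7 to 90.8 ± 3.80 CPM. Of 24 autophagy and lysosome genes, 6 rose, 7 fell (6 adjusted over the list alone) and 11 did not pass (camera adjusted p = 0.990). Their median log2 change was -0.030, while the mean, 0.10, and camera pointed up. Lamp2, a lysosomal membrane protein, rose from 150 ± 11 to 297 ± 7.14 CPM and Optn, an autophagy receptor, from 41.7 ± 6.02 to 98.4 ± 3.31. Of 14 heat shock genes, 7 rose (8 adjusted over the list alone), 4 fell and 3 did not pass (camera adjusted p = 0.630), and the collagen chaperone Serpinh1 fell from 5506 ± 372 to 2441 ± 133 CPM. The chaperones Hsp90aa1 and Hspb8 rose from 247 ± 17.4 to 477 ± 28.8 and from 75.1 ± 9.85 to 154 ± 2.40 CPM. For the 24 lists whose counts adjusted over the list alone are not given here, these were the same.

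Markers of other cell types were measured as a check on what the cultures held. Of 13 smooth muscle and pericyte markers, 10 rose and 3 fell (camera adjusted p = 0.0639). Myh11, smooth muscle myosin, rose from 24.4 ± 3.25 to 263 ± 12 CPM. Of 6 muscle markers, 2 rose and 4 did not pass (camera adjusted p = 0.198), with Des rising from 1.19 ± 0.457 to 7.34 ± 0.393 CPM. The other was Tnnc1, whose call was lost without rShh replicate 3 (edgeR adjusted p = 0.0532). Of 7 neural and Schwann markers, 1 rose, 3 fell and 3 did not pass (camera adjusted p = 0.105), and Tubb3, a neuronal tubulin, fell from 155 ± 22.8 to 19.3 ± 0.334 CPM. Of 8 epithelial keratins and desmosome genes, 2 rose, 1 fell and 5 did not pass (camera adjusted p = 0.742), and Pkp1 rose from 58.9 ± 7.69 to 175 ± 2.12 CPM while Jup fell from 95.3 ± 12.1 to 63.8 ± 1.31. The remaining 4 lists had too few members above the expression minimum for camera. Of 7 endothelial markers, 2 rose (Flt1, from 1.51 ± 0.703 to 11.5 ± 0.617 CPM, and Erg, whose call was lost without Control replicate 2, rShh replicate 2 or rShh replicate 3, at edgeR adjusted p = 0.0566, 0.0588 and 0.0551), 1 fell (Tek, from 5.71 ± 0.906 to 1.76 ± 0.079 CPM) and 4 did not pass. Of 5 macrophage and leukocyte markers, Cd74 rose, from 0 counts in the Control libraries to 20 to 55, and 4 did not pass. Of these 4, Csf1r passed without Control replicate 1 (edgeR adjusted p = 0.0113) and Cd14 without Control replicate 3 (edgeR adjusted p = 0.0359). Of 4 adipocyte markers, Cidea rose from 0.775 ± 0.490 to 2.37 ± 0.527 CPM, Lpl fell from 1.66 ± 0.381 to 0.529 ± 0.261 CPM and 2 did not pass. Ahsp, the single tested red cell marker, rose from 0.356 ± 0.230 to 8.48 ± 0.043 CPM.

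The second comparison asked the same of individual transcript isoforms. Of 13699 isoforms tested with limma on log2(FPKM + 1), 7741 changed (56.5%), 3948 higher and 3793 lower in the rShh group. This balance turned to 3574 higher and 4285 lower with quantile normalization and to 3876 and 3918 with median-ratio scaling. Of the 1631 genes with at least 2 isoforms tested, 45 had isoforms changed in both directions. The isoforms with the smallest p among those that rose were a 4-exon transcript of Aqp1 (chromosome 4, 85551503 to 85563683; 0.813 ± 0.058 to 191 ± 7.34 FPKM), a 41-exon transcript of Col18a1 (chromosome 20, 12225202 to 12332858; 6.17 ± 0.557 to 205 ± 4.51 FPKM) and a 12-exon transcript of Eif2s3y, listed at 0 in the Control group and at 28.7 ± 0.393 FPKM in the rShh group. Those that fell were a transcript of Igfbp2 (106 ± 5.95 to 4.12 ± 0.309 FPKM), one of C1qtnf3, a secreted protein of cartilage (175 ± 9.5 to 23.0 ± 1.15 FPKM), and one of Npr3 (55.9 ± 4.09 to 2.50 ± 0.381 FPKM).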

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

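Added after the data were seen were thinning, the test against 2-fold, camera on log2 CPM, edgeR on isoform counts and the count without the sex chromosomes. The count of changed genes, 8914, was 8987 with DESeq2, 7966 with limma on FPKM and 8883 after thinning. It was 5633 with a minimum of 5 FPKM (fewer genes tested), 1563 against 2-fold (a stricter question) and 1240 at an unadjusted p below 0.05 with at least 2-fold by limma on log2(FPKM + 1). Quantile normalization turned the sign of the change in 6 of the called genes and left more genes lower (4502) than higher (3599). The 7287 genes called both ways all kept their direction. DESeq2, thinning and limma on FPKM turned 0 signs. Leaving out 1 library gave 7838 to 9252 genes, 6468 to 7807 isoforms, 7 to 8 lists and a Hedgehog score difference of 0.51 to 0.56.

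The 7 gene lists past the threshold became 11 with no minimum, 0 with an estimated correlation (3 at an unadjusted p below 0.05) and 23 with fry, which asks another question; fry gave the fibrillar collagen and myofibroblast list the opposite direction (adjusted p = 0.0104). With no minimum the tendon (adjusted p = 0.0456), unfolded protein (0.00920), immediate early (0.0183) and smooth muscle (0.0120) lists also passed by camera; the cause was not tested. Quantile normalization and camera on log2 CPM each gave 10 lists; the immediate early and smooth muscle lists were added by both, the TGF-beta and BMP list by the first (adjusted p = 0.0352) and the unfolded protein list by the second (0.0314). Of 150 named genes tested, 112 kept every call, 32 lost theirs against 2-fold and 8, some of them among the 32, changed call under another setting. Dropping the eBayes trend does not apply to camera and was not run for lists.

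The groups share replicate numbers, but deviations of samples with the same number correlated at -0.06, -0.02 and -0.04, so no pairing by number was seen. The labels do not say what the numbers mean, so a shared culture or batch stays open. With the replicate block, 8440 genes (8369 shared), 7045 isoforms and 8 lists passed, the immediate early list being the one added (camera adjusted p = 0.0484), and the score p was 0.25, the smallest 3 pairs allow. No library can be left out to separate the Y-linked difference from the treatment, since it divides whole groups. Genes with few counts, such as Hhip, are limited by depth.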

Other observations

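Tests of Y-linked carry-over, of different animals and of GLI-dependent transcription, the thinning, the pathway term test, and the genes of the next paragraph were chosen only after the data were seen.

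Some transcription factor genes, picked because their counts lay near 0 in 1 group, are given here without a test of such genes as a class. Tbx15 had 4, 4 and 0 counts in the Control libraries and 512 to 643 in the rShh libraries, Tbx3 had 0 to 13 and 486 to 619, and Tbx1 had 0 to 5 and 327 to 451. Zic1 had 0 counts in each Control library and 70 to 107 in each rShh library. Tbx2, with 0, 16 and 48 counts in the Control libraries and 237 to 251 in the rShh libraries, was less clear, since its call was lost with DESeq2 (adjusted p = 0.0598). Barx1 was the opposite case, at 35.3 ± 7.64 CPM in the Control group and 0.041 ± 0.071 in the rShh group. In total 32 genes had 0 counts in all Control libraries and at least 50 in each rShh library, 28 of them not on chromosome Y, and 3 genes (Synpr, Ptchd1 and Pde1c) were the reverse. The Hox genes, whose combination marks position along the body axis, did not divide in this way. Of 32 tested, 3 rose, 11 fell and 18 did not pass, none was at 0 in 1 group with at least 10 counts in every library of the other, and the largest log2 change was 1.46 in size. The most posterior members were expressed in both groups, with Hoxa13 at 6.82 ± 0.601 and 2.91 ± 0.400 CPM and Hoxd13 at 2.81 ± 1.15 and 7.75 ± 0.979 CPM.

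The pathway terms of the deposited annotation were tested by Fisher's exact test over 5294 annotated genes. Of 301 terms, 37 were enriched among the 695 genes at least 2-fold higher and 3 among the 299 at least 2-fold lower. More genes were higher than lower, so the counts of 37 and 3 terms do not compare the directions. Fisher's test treats genes as independent, so terms whose genes move together can get p-values that are too small. Cytokine-cytokine receptor interaction led the first set (42 genes, 16.8 by chance, adjusted p = 1.45e-06). The second set was Gastric cancer (18 genes, 6.5 by chance, adjusted p = 0.0197), Basal cell carcinoma (10 genes, 2.60 by chance, adjusted p = 0.0239) and Breast cancer (17 genes, 6.55 by chance, adjusted p = 0.0239). The Hedgehog signaling pathway term itself had 2 genes at least 2-fold higher and 2 at least 2-fold lower of 38 and was not enriched in either direction (adjusted p = 1 for both), and the Wnt signaling pathway term was not enriched among the lowered genes (adjusted p = 0.393).

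The Y-linked transcripts present in every rShh library and in no Control library were weighed first. A small carry-over of male RNA would leave Eif2s3y far below its X-linked partner Eif2s3, but the lowest ratio of the 2 in the rShh libraries was 0.446, where a small carry-over was taken to give under 0.1. Were the Control cells from females and the rShh cells from males, the X-linked Kdm5c, Kdm6a and Ddx3x would be higher in Control. Their median log2 change, that of Kdm6a, was -0.063. It was judged against the median of their standard errors, 0.086, and the standard error of Kdm6a alone was 0.103. Neither measures the spread between these genes. Kdm5c fell and Ddx3x rose (log2 change -0.86 and 1.20). Ddx3x may share reads with the Y-linked Ddx3, which only the rShh libraries held, so its rise is uncertain. Eif2s3, chosen after its values were seen and not part of the test, fell as Kdm5c did (log2 change -0.35). The test therefore leaves the sex of the animals open, and loss of the Y chromosome in culture was not tested. Over the 518 X-chromosome genes tested, the median log2 change was 0.27, against 0.0045 for autosomal genes, so X genes leaned higher in the rShh group. This is opposite to the direction that female Control cells would give if a second X raised X genes in general. Whether it does so in these cells was not tested, so this lean does not decide the sex.

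That 8914 genes differ between the groups was weighed next. Larger rShh libraries are argued against, since thinning every library to the smallest total left 8883 genes. The Y-linked counts argue against groups that differed in the ligand alone. Ddx3, Eif2s3y, Kdm5d and AC241873 had 0 counts in each Control library and 912 to 7120 in the rShh libraries. Loss of the Y chromosome in culture was not tested. The shares of the 8914 changes due to different animals and to rShh cannot be told apart. The reason is that 0 libraries carry the other group's Y-linked state within a group, and the effect of rShh stays open. The 10 splits of the 6 libraries are too few for a share under 0.05. Every other split also puts libraries of both groups on each side, so the group difference counts there as spread. Few genes or isoforms can then pass, whatever the cause, and their counts do not measure chance. The real split, the 1 split with as many genes, gave 8914 genes with edgeR, and the highest other gave 0 (137 at an unadjusted p below 0.05, 0 with limma). For isoforms the real split, again the 1 with as many, gave 7741 and the highest other 6. For gene lists the real split gave 7 and the others 3 to 10, with 3 splits giving at least 7, the real one included. The number of lists past camera's preset correlation therefore does not set the real split apart.

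The third pattern was the rise of Ptch1. A normalization or scaling effect is argued against, since its lowest log2 change among 10 other settings was 0.81, with an adjusted p of at most 0.000464 (lowest 5.99e-29). These settings covered scaling, tool and thinning. They also covered the pseudocount, expression minimum and variance model, which do not rescale the libraries. GLI-dependent transcription raised by the ligand may be the cause, and the other targets do not decide it. Gli1 and Hhip were to rise with Ptch1, and 0 of them passed, but Hhip had too few counts to be tested and Gli1 passed without Control replicate 1 (edgeR adjusted p = 0.00131). GLI-dependent transcription raised by the ligand therefore cannot be told apart from a difference between the cells of the groups.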
